A study of Rattus norvegicus with 2 samples.

How the data were processed

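RNA from rat oligodendrocyte precursor cells (OPCs), the glial progenitors that differentiate into the myelin-forming oligodendrocytes of the central nervous system, was sequenced after transfection with an empty vector or with a Slit1 construct. Per the labels' protocols, total RNA was extracted with a column kit and libraries were prepared by standard Illumina protocols. There were 2 libraries, 1 per group. The library labelled control is called vector here and the library labelled Slit1 is called Slit1. The time between transfection and harvest is not given in the sources used here.

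The authors deposited 1 table of 17455 genes with NCBI gene numbers and symbols, holding 3 values per gene and library. Per the file headers these are FPKM, TPM and read counts. The deposited FPKM values summed to 459452 in vector and 473673 in Slit1. The deposited TPM values were scaled by the authors and summed to 1000000 per library. The deposited read counts are estimated counts and need not be whole: 26.1% of them in vector and 31.4% in Slit1 lay within 0.01 of a whole number. The genome build mRatBN7.2 is named in the submitters' processing notes. The aligner, the counter, the annotation, the handling of strand and any filter are not given in the sources used here. Of the gene numbers, 17205 (98.6%) were found in the RefSeq gene table of another assembly, GRCr8, which was used only for current symbols, gene types and gene neighbourhood; 16980 were protein-coding and 178 pseudogenes there. No genome was used, so no coordinates are given. Mitochondrially encoded genes were not analysed here. The number of value columns belonging to other samples was 0.

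Estimated counts summed to 18817462 in vector and 18998770 in Slit1. A count of 0 allows up to 3 counts, which at a gene of median length was worth 0.128 TPM in vector and 0.123 TPM in Slit1. For each gene the ratio of the deposited TPM values was given with an exact (Clopper-Pearson) 95% interval for the ratio of 2 Poisson counts, computed from the estimated counts rounded to whole numbers and carried to the TPM ratio. These intervals and floors cover counting error only and say nothing of the spread between cultures.

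With 1 library per group there is no replicate check on any difference, and no p-value was computed. The main measure was the difference of log2(TPM + 1), Slit1 minus vector, over the 13175 genes whose mean in both libraries was at least 1 TPM; the pseudocount of 1 understates the change of low genes. TPM was taken as the main unit because it is the authors' scaling to an equal total. Genes were called higher or lower when they differed at least 2-fold on this scale. For 37 gene lists, 36 of which had a measured member, the number of members at least 1.5-fold higher or lower was counted. The median of each list was placed among the medians of 10000 random lists of the same size, drawn with replacement within 20 bins of mean expression. A list is called outside when it lies below percentile 2.5 or above percentile 97.5. If list members varied independently, chance would put 1.8 of the 36 lists there. Members of a list can move together between any 2 cultures, and some lists share members. More lists than that can therefore lie outside without an effect of Slit1. These percentiles describe this pair of libraries. Lists, thresholds, the rule for named genes and the other alternatives were fixed before the data were examined; alternatives using counts per 1000000 (CPM), FPKM, a correction for gene length (lowess, span 0.3) and the omission of genes with only an identifier were chosen after seeing the data.

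By the rule for named genes the text names every measured Slit ligand and Robo receptor, the 12 genes with the largest and the 12 with the smallest log2 difference among genes with a symbol at 5 TPM or more in the higher library, up to 4 members with the largest absolute difference from each list, and 15 lineage genes whatever their value. A gene that the rule takes in is not reported here. A few genes outside this rule are marked as chosen after their values were seen. The alternatives were pseudocounts of 0.1 and 5, floors of 0 and 5 TPM, fold limits of 1.5 and 3, centring on the median gene, edgeR TMM factors on the rounded counts, intervals wholly beyond 2-fold, lists without shared members, and 10 bins. Since the table holds counts, a trimmed mean meant for tables without counts was not run.

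The calculation was tested on simulated data drawn from the real gene means and library totals with Poisson noise. In 100 simulations without any difference the median number of genes at least 2-fold higher was 3 and the largest was 8, and the median number lower was 4 and the largest 9. With 200 planted genes, the 2-fold rule called 0% of those planted at 1.5-fold, 92% of those at 3-fold and 100% of those at 8-fold, and 95.3% of the counting intervals held the true ratio. The simulations held neither spread between cultures nor reads divided between genes, so they check the calculation only. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 (TMM factors only) were used.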

Results

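The transcriptomes of rat OPCs transfected with vector or with Slit1, a secreted ligand of the Robo receptors, were compared by RNA sequencing, with 1 library in each group. The series asks how overexpression of Slit1 affects gene expression during OPC differentiation. The libraries held 18817462 estimated counts in vector and 18998770 in Slit1, and the 10 most abundant genes took 5.12% and 5.13% of them. Across the 13175 genes with a mean of at least 1 TPM, log2(TPM + 1) correlated between the libraries with r = 0.981 (across genes, which are not independent replicates). Since no group had a replicate, every difference given here lacks a replicate check. The intervals of gene ratios describe counting error in these libraries, not the spread between cultures.

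The overexpressed gene was examined first. Slit1 was present at 1.70 TPM (72.2 estimated counts) in vector and at 229.7 TPM (10133 estimated counts) in Slit1, a ratio of 135 (95% counting interval 107 to 173). On the log2(TPM + 1) scale the difference was 6.42. Counts from the construct and from the chromosomal gene cannot be separated in a table per gene. The other ligands were scarce: Slit2 measured 1.06 and 1.13 TPM in vector and Slit1, and Slit3 measured 0.11 TPM in both. Among the receptors, Robo1 measured 17.2 TPM in vector and 16.1 TPM in Slit1 (ratio 0.934, interval 0.856 to 1.02), and Robo2 measured 19.5 and 20.9 TPM (ratio 1.07, interval 1.004 to 1.15). Robo3 was detected with 2 and 4 counts. Robo4, listed under an older identifier (LOC100911068), had 4 and 1.75 estimated counts. None of the 22 measured intracellular partners of Slit-Robo signalling differed by 1.5-fold or more in TPM (2 were higher with the median gene set to 0, with edgeR TMM factors, in CPM and in FPKM), and the list's median of -0.11 lay at percentile 12.5. The members that differed most were Myo9b, a RhoGAP (1.49-fold higher), the kinases Abl1 (1.47-fold higher) and Fyn (1.45-fold higher), and Srgap3, a GTPase-activating protein that binds Robo (1.43-fold lower).

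Of the 13175 genes, 164 were at least 2-fold higher and 85 at least 2-fold lower in the Slit1 library, and without genes that have only an identifier these numbers were 138 and 53. Of the 109 measured members of the 4 oligodendrocyte lists, 34 were among the higher genes and 0 among the lower. Among genes with a symbol and at least 5 TPM in the higher library, those that followed Slit1 by log2 difference included Mbp and Mag, which encode myelin proteins, Cldn11, the claudin of myelin tight junctions, Pnlip (pancreatic lipase), Enpp6, a choline phosphodiesterase of newly formed oligodendrocytes, Cdk18, the tubulin gene Tubb4a, Tmem163, Tppp, a tubulin polymerization factor, and Rab33a. The ratio of the last of these, Rab33a, was 4.39 (9.20 against 40.4 TPM, interval 3.43 to 5.68). Tubb4a measured 136.9 TPM in vector and 677 TPM in Slit1 (4.94-fold, interval 4.73 to 5.17), and Pnlip measured 29.4 and 193.7 TPM (6.58-fold, interval 5.92 to 7.34).

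The 12 genes lowest by the same rule were Cpne1, Mt1m, Ptar1, Ppial4d, Dio2, Lrrc58, Rnf144b, Ro60, Sesn3, Socs4, Akr1b8 and Mob1b. Dio2, the deiodinase that activates thyroid hormone, measured 56.3 TPM in vector and 17.9 TPM in Slit1 (3.13-fold lower, interval 2.92 to 3.37). Sesn3, a sestrin, was 2.89-fold lower (interval 2.59 to 3.24), and the ubiquitin ligase gene Rnf144b was 3.40-fold lower (interval 2.84 to 4.09). Cpne1 measured 24.2 TPM in vector and 0.42 TPM in Slit1, but the gene overlaps Rbm12 and the summed counts of this pair differed by less than counting error (ratio 0.992, interval 0.920 to 1.07). Mt1m (36.3 against 0 counts, at least 12.5-fold lower against a floor of 3 counts, with a lower limit of 9.65-fold by the counting interval) is annotated as a pseudogene. Ppial4d (32.8 against 5.25 counts) and Akr1b8 (994 against 386 counts, 2.68-fold lower, interval 2.38 to 3.02) belong to families of similar genes. The values of these genes are uncertain if reads were divided between similar genes, which was not tested at the level of reads. At a limit of 1.5-fold the balance of the sets was different: 490 genes were higher and 637 lower, a share of 43.5% higher that became 54.3% with the median gene set to 0, 54.0% with edgeR TMM factors, 52.3% in CPM and 54.3% in FPKM.

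**Figure D1:**
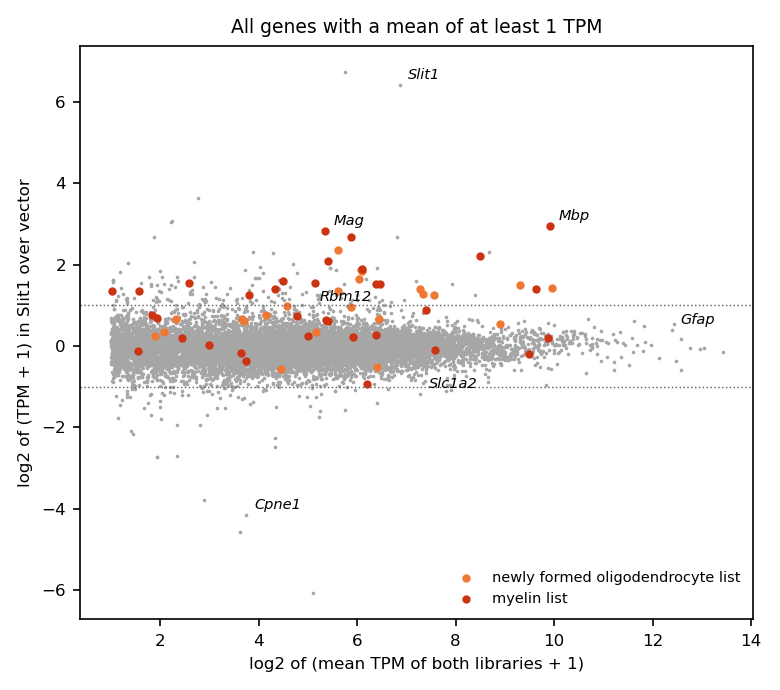
Each grey point is a gene with a mean of at least 1 TPM; the horizontal axis is log2 of (mean TPM of both libraries + 1) and the vertical axis is log2 of (TPM + 1) in the Slit1 library over vector. Orange points are the newly formed oligodendrocyte list, red points the myelin list, and dotted lines mark 2-fold; most coloured points lie above 0, with Mbp at 2.94 and Mag at 2.82, while Slit1 lies at 6.42.

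Genes that mark the start of oligodendrocyte differentiation were higher in the Slit1 library as a group. Of 23 measured markers of committed precursors and newly formed oligodendrocytes, 17 were at least 1.5-fold higher and 0 were lower by that amount, and the median log2 difference was 0.97, above every one of the 10000 random lists (percentile 100). Enpp6 was 5.41-fold higher (15.02 against 81.2 TPM, interval 4.95 to 5.91). Bmp4, a secreted morphogen, was 3.74-fold higher (interval 3.34 to 4.18), the plexin gene Plxnb3 3.65-fold higher (interval 3.45 to 3.87) and Chn2, a Rac GTPase-activating protein, 3.21-fold higher. Bcas1 measured 331.6 TPM in vector and 939.2 TPM in Slit1 (2.83-fold, interval 2.76 to 2.91), and Gpr17, a receptor of the transitional stage, measured 109.8 and 263 TPM (2.40-fold, interval 2.32 to 2.47).

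Myelin genes were higher in the Slit1 library as a group. Of 34 measured myelin and mature oligodendrocyte genes, 22 were at least 1.5-fold higher and 1 was lower, with a median log2 difference of 0.82 at percentile 100. Mbp, which encodes myelin basic protein, measured 220.5 TPM in vector and 1704 TPM in Slit1 (7.73-fold, interval 7.47 to 7.998). Mag measured 9.07 and 70.2 TPM (7.74-fold, interval 6.67 to 9.02), and Cldn11 14.7 and 99.9 TPM (6.78-fold, interval 5.90 to 7.83). Cnp, an enzyme of non-compact myelin, was already at 437.1 TPM in vector and reached 1153 TPM in Slit1 (2.64-fold, interval 2.57 to 2.71). Mog, a protein of the outermost myelin layer that appears late, was scarce in both libraries, with 3.88 and 33.4 estimated counts (ratio 12.9, interval 4.58 to 49.99). The member that was lower was Car2, encoding a carbonic anhydrase (95.04 against 49.6 TPM, named after its value was seen).

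Precursor markers lay on both sides of 0. Of 26 measured, 7 were at least 1.5-fold higher, 3 were lower (1 under every other scaling) and 16 lay between, and the median of 0.07 lay at percentile 94.2; it lay outside the range of random lists in 3 of 12 alternatives, at percentile 97.8 with edgeR TMM factors, 98.2 in CPM and 99.94 with the gene length trend removed. Pdgfra, the receptor for the growth factor that maintains OPCs, measured 40.2 TPM in vector and 41.4 TPM in Slit1 (ratio 1.03, interval 0.970 to 1.09), and Cspg4 (NG2) measured 10.1 and 10.3 TPM (ratio 1.03, interval 0.925 to 1.14). The higher members included Tnr, a matrix glycoprotein (3.10-fold), the sialidase gene Neu4 (2.60-fold), Scrg1 (2.33-fold) and Matn4 (2.59-fold), and the lower ones included the glutamate receptor gene Gria3 (1.65-fold).

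**Figure D2:**
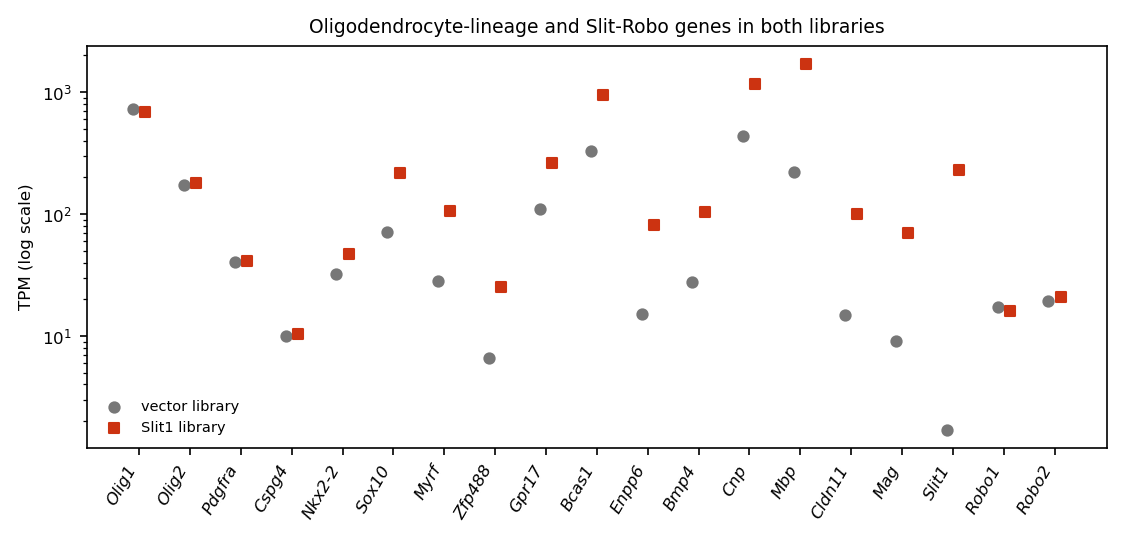
The vertical axis is TPM on a log scale and the horizontal axis lists lineage and Slit-Robo genes; grey circles are the vector library and red squares the Slit1 library, 1 library each, without error bars. Olig1, Olig2, Pdgfra, Cspg4, Robo1 and Robo2 lie at nearly equal heights, while Mbp lies at 220.5 and 1704 TPM and Slit1 at 1.70 and 229.7 TPM.

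The transcription factors of the lineage went in both directions. Of 29 measured, 6 were at least 1.5-fold higher and 5 lower; the median of -0.03 and the mean of 0.19 differed in sign, and the median lay at percentile 50.9 and was above 0 under each other scaling. Olig1 (730.1 and 686 TPM, ratio 0.940, interval 0.917 to 0.963) and Olig2 (171.4 and 178.1 TPM, ratio 1.04, interval 0.994 to 1.09), which are expressed throughout the lineage, differed little. Among the 6 higher factors were Myrf, the myelin regulatory factor (3.82-fold, 28.0 against 106.8 TPM, interval 3.59 to 4.06), Zfp488 (3.85-fold, interval 3.31 to 4.50), Sox10 (3.05-fold, 71.4 against 218 TPM, interval 2.90 to 3.22) and Nkx6-2 (3.80-fold, interval 2.48 to 6.01, from 28.4 and 98.6 counts). Nkx2-2 was 1.47-fold higher (interval 1.32 to 1.65). The 5 lower factors, named after their values were seen, were Sox11 (1.82-fold), Zeb2 (1.65-fold), Zfp24 (1.63-fold, with counts of 3482 and 2761), Sox5 (1.60-fold) and Tcf4 (1.53-fold). Under every other scaling 3 factors were lower.

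Genes of fatty acid and myelin lipid synthesis and of sterol synthesis were measured as separate lists. Of 23 measured genes of fatty acid synthesis and myelin lipids, 5 were at least 1.5-fold higher and 0 lower (median 0.09, percentile 94.5, inside the range of random lists). It lay outside in 3 of 12 alternatives, at percentile 97.95 with edgeR TMM factors, 97.8 in CPM and 99.91 with the gene length trend removed. The higher genes were led by Fa2h, the fatty acid hydroxylase of myelin (3.23-fold, interval 2.77 to 3.79), Ugt8, the enzyme that makes galactocerebroside (2.93-fold, interval 2.74 to 3.12), Gal3st1, the enzyme that makes sulfatide (2.78-fold), and Acsl3 (1.75-fold). Without members shared with other lists 1 gene was higher and the median was 0.00 at percentile 59.2. None of 24 measured sterol synthesis genes differed by 1.5-fold in TPM (2 were higher under every other scaling). Yet the list's median of 0.21 (95% bounds from the ranks of the members -0.03 to 0.33) lay at percentile 99.99. The largest were Fdps (1.498-fold as a TPM ratio), Mvk (1.48-fold), Acat2 (1.43-fold) and Mvd (1.42-fold).

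Genes of DNA replication and mitosis were slightly higher as a list, and the joint list of cell cycle inhibitors and p53 targets had a median below 0. Of 50 measured genes of DNA replication and mitosis, 5 were at least 1.5-fold higher (8 with edgeR TMM factors or in CPM) and 0 lower, with a median of 0.31 at percentile 100; Birc5 (1.84-fold, interval 1.45 to 2.36), Ttk (1.78-fold), Tk1 (1.56-fold) and Ube2c (1.57-fold) led. Of 28 measured cell cycle inhibitors and p53 targets, 6 were lower and 1 higher, with a median of -0.34 at percentile 0. The 95% bounds of this median from the ranks of the members reached 0 (-0.52 to 0.003), and the mean was -0.21. The number lower was 3 with the median gene set to 0 or in FPKM, and 2 of 27 with edgeR TMM factors or in CPM. Eda2r was 1.92-fold lower (interval 1.78 to 2.06) and Mdm2, the p53 ubiquitin ligase, 1.57-fold lower (interval 1.499 to 1.65), while Pmaip1 rested on 19.99 and 9 counts. The member that was higher was Cdkn1c, the cyclin-dependent kinase inhibitor p57 (29.0 against 73.1 TPM, 2.52-fold, interval 2.27 to 2.81). The 7 measured cyclin-dependent kinase inhibitor genes lay on both sides of 0, from a log2 difference of -0.56 in Cdkn1a, named after its value was seen, to 1.31 in Cdkn1c. Cytosolic ribosomal protein genes were higher by a small step, with a median of 0.19 at percentile 100 over 62 genes, of which 1, Rpl30, was 1.5-fold higher at 14.1 and 26.1 counts; Rpl7a, Rps2 and Rpl28 were 1.42-fold, 1.39-fold and 1.31-fold higher, and reads of these genes can be shared with their many pseudogenes.

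Genes of growth factor signalling were lower in the Slit1 library. Of 30 measured growth factor receptors and MAPK feedback genes, 8 were at least 1.5-fold lower and 2 higher, with a median of -0.35 at percentile 0. The 2 higher members lay near the limit, with log2 differences of at most 0.63. Fgf2 was 1.97-fold lower (interval 1.60 to 2.42), Spry4, a feedback inhibitor of receptor tyrosine kinases, 1.93-fold lower (interval 1.76 to 2.12), Ccnd1 (cyclin D1) 1.86-fold lower (521.6 against 280.7 TPM, interval 1.81 to 1.91) and Phlda1 1.81-fold lower (interval 1.64 to 2.002). Of 30 measured immediate early genes, 5 were lower (3 with the median gene set to 0 or in FPKM) and 0 higher (median -0.27, percentile 0.03), including Egr2 (2.43-fold, interval 1.96 to 3.02), Egr1 (1.75-fold), the MAPK phosphatase gene Dusp6 (1.70-fold) and Klf4 (1.58-fold).

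Several stress-related lists were also lower. Of 24 measured NRF2 targets of the oxidative stress response, 4 were at least 1.5-fold lower and 0 higher (median -0.30, percentile 0): Slc7a11, the cystine transporter (2.10-fold, interval 1.98 to 2.23), Hmox1, heme oxygenase (1.90-fold, interval 1.79 to 2.03), Srxn1 (1.74-fold) and Nqo1 (1.52-fold). Under every other scaling Nqo1 was lower by less than 1.5-fold (in FPKM 323.2 against 219.4). Of 26 measured amino acid starvation genes, 5 were lower (3 with edgeR TMM factors, in CPM and in FPKM) and 0 higher (median -0.21, percentile 0.68), among them Slc7a11, Slc6a9 (1.67-fold), Cth (1.67-fold) and Trib3 (1.81-fold). Without members shared with other lists this list lay at percentile 2.56, inside the range of random lists. Of 18 heat shock and metallothionein genes, 2 were lower, Mt1m and Mt1 (1.68-fold), and 0 higher (median -0.21, percentile 0.42; percentile 6.64 in CPM); Mt2A was 1.31-fold and Chordc1 1.28-fold lower. The unfolded protein response list (median 0.00, mean -0.04, percentile 65.2) had 1 lower member of 30, Trib3; Dnajb9 and Edem1 were 1.51-fold and 1.49-fold lower and Derl3 1.34-fold higher as TPM ratios. The interferon list (median -0.07, percentile 44.5) had 4 higher and 2 lower of 42 (1 and 1 of 34 in FPKM): Mx1 (2.54-fold higher), Oas1b (1.81-fold higher), Trim25 (1.89-fold lower) and Cxcl9, which rested on 6.94 and 15 counts, differed most. In the NF-kB and cytokine list 5 of 26 were lower (1 with edgeR TMM factors or in CPM) and 1 higher, and its median of -0.15 lay at percentile 2.60, inside the range, but below percentile 2.5 in 7 of 12 alternatives. Lif (1.96-fold lower in TPM, with counts of 1304 and 933), Cxcl2 (2.13-fold) and Cxcl6 (1.66-fold) were lower, and Lcn2, lipocalin 2, was higher (1277 against 2034 TPM, 1.59-fold).

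Among developmental pathways, only the Wnt list lay outside the range of random lists on the main measure. Of 27 measured Wnt genes, 6 were lower (3 of 24 in FPKM), Ccnd1 among them, and 2 higher (median -0.27, percentile 0.13); the receptor gene Fzd3 was 1.94-fold lower (interval 1.73 to 2.17) and the secreted Wnt antagonist gene Sfrp1 1.62-fold lower, while Tcf7l2, a Wnt effector that is also a marker of newly formed oligodendrocytes, was 1.98-fold higher (interval 1.85 to 2.12). The Notch list of 20 had 2 higher and 1 lower member (median -0.09, mean 0.04, percentile 32.5): Jag2 was 4.77-fold higher from 36 and 177 counts, Hes5 3.70-fold higher from 9 and 48 counts, Jag1 1.64-fold lower, and Cntn1 1.48-fold lower as a TPM ratio. The BMP and TGF-beta list of 30 had 3 higher, including Bmp4 and Id3 (1.56-fold), and 2 lower, Ltbp1 (1.70-fold) and Tgfbr2 (1.64-fold), with a median of -0.14 at percentile 11.2. The Hedgehog list of 8 had 2 lower members, Gli3 (2.05-fold) and Gas1 (1.58-fold), and its median of -0.05 lay at percentile 56.2; Ptch1 and Smo had ratios of 1.10 and 0.946. The list of other axon guidance genes had 5 higher and 4 lower of 44 (5 and 1 of 41 in FPKM; median 0.01, mean -0.02, percentile 89.9), with Plxnb3, Ephb1 (2.57-fold higher), Efna1 (1.96-fold higher) and Ntn4 (1.70-fold lower) at its ends.

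Markers of other cell types were measured beside the oligodendrocyte genes. Of 27 measured astrocyte markers, 4 were at least 1.5-fold lower and 1 higher, with a median of -0.01 at percentile 44.2; the median was 0.04 in CPM. The glutamate transporter gene Slc1a2 was 2.29-fold lower (215.4 against 94.1 TPM, interval 2.16 to 2.43), Gja1 (connexin 43) 1.71-fold lower, F3 1.65-fold lower and Cldn10 1.63-fold lower. Gfap, an intermediate filament of astrocytes named here after its value was seen, was among the 10 most abundant genes in both libraries, at 4694 TPM in vector and 6130 TPM in Slit1 (1.31-fold, interval 1.30 to 1.32). The libraries therefore need not come from oligodendrocyte-lineage cells alone. The share of each cell type in these cultures was not measured. Any list difference may include a difference in cells outside the lineage. Of 25 measured neuron markers, 3 were higher and 4 lower (3 and 1 of 24 in FPKM); the median of 0.11 lay at percentile 98.6, but reversed in sign in CPM. Sst (8 and 24 counts), Ina (1.68-fold higher), Elavl4 (1.87-fold lower) and Nefl (29.99 and 12 counts) differed most. The 8 measured microglia markers had 1 higher (Cd68, 19 and 39 counts) and 1 lower (Cd14, 1.73-fold), with a median of -0.03 at percentile 50.01; Lgmn was 1.21-fold higher and Lyz2 had 16 and 14 counts. The 10 measured endothelial, mural and fibroblast markers had 1 higher (Tagln, 2.21-fold) and 1 lower (Flt1, 2.004-fold), with a median of 0.00, a mean of -0.05 and a percentile of 71.7; Igfbp2 and Myh11 were 1.48-fold and 1.28-fold lower. The Schwann cell list of 10, which shares Sox10 with the oligodendrocyte lineage, had 3 higher, including Sox10 and Cadm4 (1.57-fold), and 1 lower (Egr2), with a median of -0.04, a mean of 0.26 and a percentile of 39.2. The 7 measured ependymal and choroid plexus markers had 1 lower, Dynlrb2 (22 and 11 counts), and a median of -0.28 at percentile 5.78; Otx2, Dnah11 and Enkur were 1.75-fold, 1.49-fold and 1.22-fold lower. Of 25 reference genes 0 differed by 1.5-fold (median -0.03, percentile 32.0); Ywhaz, Tfrc and Hprt1 were 1.46-fold, 1.41-fold and 1.33-fold lower and Rplp0 1.27-fold higher.

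**Figure D3:**
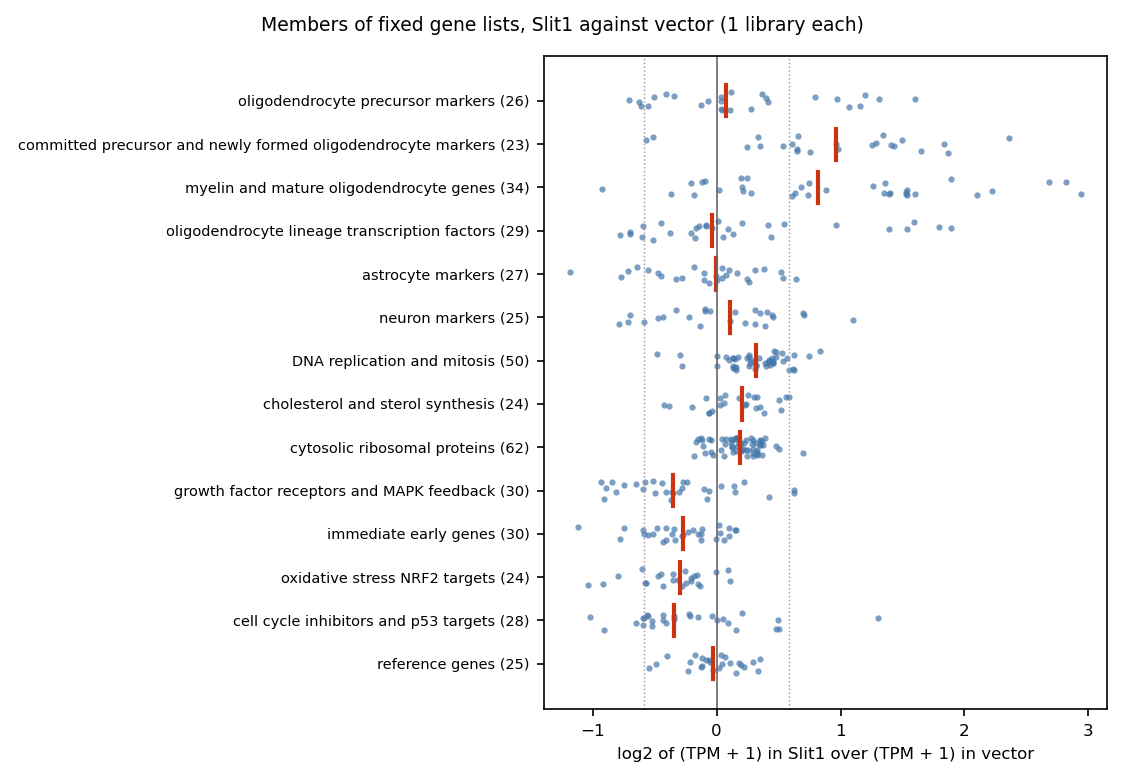
Each blue point is a measured member of a fixed list (number in parentheses), placed on the horizontal axis by log2 of (TPM + 1) in the Slit1 library over vector; red bars are list medians, dotted lines mark 1.5-fold, and the vertical scatter within a list has no meaning. The medians of the newly formed oligodendrocyte (0.97) and myelin (0.82) lists lie to the right, those of growth factor feedback (-0.35) and cell cycle inhibitors with p53 targets (-0.34) to the left, and reference genes lie at -0.03.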

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

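Of the 13 lists outside the range of random lists, 10 were outside under all 12 alternatives: newly formed oligodendrocyte, myelin, DNA replication, sterol synthesis, ribosomal protein, growth factor feedback, immediate early, NRF2, p53 and Wnt. Centring on the median gene shifts all genes alike and could move a percentile only through the random draws. The newly formed median ranged from 0.83 to 1.12 and the myelin median from 0.56 to 1.07. The neuron list reversed to -0.0069 with edgeR TMM factors, to -0.036 without a floor and to -0.018 in CPM. Heat shock and amino acid genes kept their sign but came inside the range under 2 and 1 alternatives. The BMP and TGF-beta (percentile 1.89), ependymal (2.2), Schwann (99.87) and axon guidance (99.28) lists each came outside under 1 alternative. The oxidative phosphorylation list came outside under 2. Lists near 0 also took the other sign under at least 1 alternative: lineage transcription factors, astrocyte, microglia, Schwann, endothelial, reference, Hedgehog, ion channel, unfolded protein, oxidative phosphorylation and axon guidance. List counts of 1 to 3 members in a direction reached 0 under at least 1 alternative for lists that include the unfolded protein, interferon, hypoxia, ribosomal, Notch, microglia, endothelial, ependymal, ion channel and Schwann lists. The log2 difference of Slit1 (6.42) became 6.996 and 5.13 with pseudocounts of 0.1 and 5, 6.80 with TMM factors, 6.79 in CPM and 5.95 in FPKM, as the pseudocount weighs differently on each scale. The 164 higher genes became 81 with a pseudocount of 5, 490 at 1.5-fold and 48 at 3-fold. The 85 lower genes became 180 and 32 with pseudocounts of 0.1 and 5, 51 with a floor of 5 TPM, 44 in FPKM, 53 without identifier-only genes, 637 and 20 at 1.5-fold and 3-fold, and 46 with the interval wholly beyond 2-fold. Of the 24 genes named by size, 19 to 24 kept their place under 8 alternatives, and 0 called named genes reversed. CPM, FPKM, the length correction and the omission of identifier-only genes were chosen after seeing the data. No paired analysis was possible because each group has 1 library. Depth limits Slit3, Robo3, Robo4 and Mog, which have 5 or fewer counts in at least 1 library.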

Other observations

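All tests of technical explanations in this part were chosen after the results were seen. Adhesion, matrix and excitability genes moved in both directions in the Slit1 library. Of 39 measured extracellular matrix genes, 5 were at least 1.5-fold higher and 3 lower (median -0.09, percentile 17.6). The higher ones included Tnr (3.10-fold), Bcan (brevican, 123.5 against 358.2 TPM, 2.90-fold, interval 2.79 to 3.02) and Fbln2 (2.01-fold); Lox, a collagen cross-linking enzyme, was 2.18-fold lower. Of 36 actin and adhesion genes, 4 were higher, among them Tagln (2.21-fold) and Wasf1, a regulator of actin branching (1.90-fold), and 5 were lower, among them the integrin gene Itgav (172.4 against 96.7 TPM, 1.78-fold) and Msn (moesin, 1.73-fold), with a median of -0.08 at percentile 14.3. Of 27 ion channel and synaptic genes, 3 were lower, Kcnj16 (2.32-fold), Grm5 (1.66-fold) and Gria3 (1.65-fold), and 1 higher, Grin3a (2.10-fold), with a median of -0.13 at percentile 15.1.

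Energy metabolism genes differed little. None of 44 nuclear genes of oxidative phosphorylation differed by 1.5-fold (median 0.05, percentile 75.5; percentile 98.1 in CPM, and a median of -0.05 with the gene length trend removed); Ndufb8 and Ndufb5 were 1.41-fold and 1.31-fold higher, Ndufs1 and Uqcrb 1.36-fold and 1.22-fold lower. Of 35 hypoxia and glycolysis genes 1 was higher (Ankrd37, 6 and 13 counts) and 1 lower (Adm, 1.70-fold), with a median of 0.04 at percentile 83.8; Slc2a3 was 1.79-fold lower and Pfkl 1.38-fold higher as TPM ratios. Abundant glial genes, chosen after their values were seen, went apart: Ptn (7360 against 4849 TPM), Glul (2879 against 1907 TPM) and Fabp7 (3426 against 2471 TPM) were 1.52-fold, 1.51-fold and 1.39-fold lower, while Apoe (2497 against 3849 TPM) was 1.54-fold higher.

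Newly formed oligodendrocyte and myelin genes were higher in the Slit1 library, while long genes tended to be lower (median log2 difference 0.08 in the shortest decile and -0.17 in the longest); with this trend removed both list medians were at least 0.82, which argues against gene length as the whole cause. Counting error is argued against as well: of all 57 measured members of both lists, 45 had a counting interval above 1 and 6 below 1, where counting error alone would put 1.4 on each side. A larger share of oligodendrocyte-lineage cells of every stage would raise precursor genes as much, if only lineage cells express them. The upper 95% bound of the precursor median (0.42) lay below the lower bound of the newly formed median (0.61). This held in 11 of 12 alternatives but not without shared members (0.97 against 0.34). These bounds rest on the ranks of list members taken as independent, and do not cover counting error or the spread between cultures. Of the 26 precursor genes, 7 were at least 1.5-fold higher and 3 lower, so their median cannot settle the question. For the myelin list, the upper counting bounds of Olig1, Olig2, Pdgfra and Cspg4 (log2 ratio at most 0.19) lay below its lower bound (0.24). This held in 11 of 12 alternatives but not with the length trend removed (0.31 against 0.18). Without a floor the bounds lay close (0.189 against 0.195). Use of 10 bins and centring could not change either comparison, nor could leaving out identifier-only genes for the myelin list. The bounds are unlike: those of the genes cover counting error of TPM ratios, that of the list the ranks of its members. These 4 genes were picked after their values were seen, and the other fixed lineage factors, Sox10, Nkx2-2 and Myrf, were higher. Sox10 alone was 3.05-fold higher (interval 2.90 to 3.22). As the lineage genes went different ways, they cannot settle whether the share of lineage cells differed. Whether Slit1 or some other difference between these cultures is the source stays open. Such a difference could be a larger share of lineage cells or a different starting share of differentiated cells. With 1 library per group these cannot be told apart. A candidate explanation to test with replicate cultures is that Slit1 promotes the step from precursor to early oligodendrocyte. It was not tested here, and not every list followed the newly formed and myelin lists. The lineage transcription factors went both ways (6 higher, 5 lower). Genes of DNA replication and mitosis were higher as a list (median 0.31).

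Some genes were present in one library and nearly absent in the other. Cpne1 had 688.3 estimated counts in vector and 24.3 in Slit1, while Rbm12, which overlaps it in the RefSeq table, had 687.7 and 1354; their sums were 1376 and 1378, a ratio of 0.992 in CPM (interval 0.920 to 1.07), consistent with the same reads being assigned to one gene in one library and shared in the other. Of 30 genes differing at least 4-fold, 13 (43.3%, exact interval 25.5% to 62.6%) were pseudogenes by gene type or had a copy-like symbol. A copy-like symbol ended in -ps or in l and a number. Among all genes above the floor 8.02% met this rule. The rule also takes in ordinary genes such as Rpl3 and Ccl2, so 8.02% is not the share of true copies. Examples are LOC100360117, now a pseudogene of Rpl8 (0 and 762.3 counts), and LOC501116, now an Eif4g2-like gene (1528 and 0.16 counts). Division of reads between near-identical copies may therefore account for these, and this was not tested at the level of reads; no biological explanation was tested.

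The growth factor feedback, immediate early and NRF2 lists and the joint list of cell cycle inhibitors and p53 targets were lower in the Slit1 library. The median closest to 0 among these 4 lists was -0.27 with the gene length trend removed, so length does not account for them. With the median gene set to 0 it was -0.23. Centring only takes off the overall median (-0.05), so this shows that the lists lay below the median gene and tests no other scaling. Under all 12 alternatives, which include edgeR TMM factors, CPM and FPKM, the 4 lists stayed at or below percentile 0.21. A general stress difference between both transfections stays open: of 5 other stress lists, 2 (heat shock and amino acid starvation) lay below percentile 2.5, and the NF-kB (percentile 2.60), unfolded protein and interferon lists did not. This tally turns on the cut-off. Of 12 alternatives, the heat shock list lay below it in 10, amino acid starvation in 11 and NF-kB in 7. The amino acid list, which shares Slc7a11 with the NRF2 list, came inside without shared members. GC content was not examined here. An effect of Slit1 and a difference between these cultures in growth factor exposure, handling or the shares of cell types and stages all stay open. With 1 library per group they cannot be parted.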
